A study of Mus musculus with 15 samples.

How the data were processed

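Bulk RNA sequencing had been carried out on livers of male C57BL/6J mice, 15 libraries in 5 groups of 3. Per the labels' protocols, RNA was purified with a Qiagen column kit and made into stranded, poly(A)-selected Illumina libraries. The adeno-associated virus of serotype 8 (AAV8) carried either a liver-specific promoter of the thyroxine binding globulin gene (TBG) driving Activin A or green fluorescent protein (GFP), or an H1 promoter driving a short hairpin RNA against Gpnmb or a scrambled hairpin. Per the labels' protocols, 4 groups ate a diet that produces non-alcoholic steatohepatitis (NASH) with sugar water for 16 weeks, and a GFP group ate standard chow for 16 weeks.

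The deposited data were 3 tables, one per comparison, each with the 6 libraries of its 2 groups. Per the file headers, each table gave whole-number counts per gene and library, which the authors had not normalized, and these counts were used for every test. The tables also held the authors' log2 fold changes, per the file headers, with the authors' p-values and adjusted p-values, and other columns the authors deposited per gene, such as gene length and position. The authors' own fold changes and p-values served only for a comparison of calls. Per the submitters' processing notes the genome build was GRCm38 (mm10). The aligner, the counting program, its strand setting and the annotation release are not given in the sources used here. Because the way reads shared by near-identical genes were counted is not given, values of the major urinary protein (Mup), Cyp2a, Cyp2b, Cyp4a, Serpina1, Saa, Orm and globin families, and of genes that overlap another on either strand, are uncertain as to which family member or strand they come from.

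The deposited files held 23962 genes (diet), 24357 (Activin A) and 24671 (Gpnmb), each with at least 2 counts over its libraries, and no row without a gene. For the diet, 21 gene symbols, and in each of the other files 22, had been turned into dates and were restored from the gene identifier. A missing p-value in the deposited tables (6, 5 and 4 genes) stood beside an adjusted p of 1. The NASH diet GFP libraries appear in both the diet and the Activin A table, and none of the 23148 genes in both differed in these counts. Libraries held 15276879 to 23467867 counts. Pairs of libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of at least 5.54, so no library was counted as a copy of another. Nothing in the labels says whether libraries of a group came from separate animals, so the p-values measure the spread between these samples, which could be partly technical. The labels give no date or batch.

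Genes were filtered with filterByExpr (minimum count 10), normalized with the trimmed mean of M values (TMM) and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with only the 2 groups of the comparison in the fit and no covariate. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. All p-values are two-sided, and the standard error (SE) of a log2 fold change was its size divided by the square root of the F statistic. Levels (CPM) are counts scaled to the same library total (unit 1e6) with TMM factors over all 15 libraries, given as mean and standard deviation (SD) of 3 libraries. The tables were joined for these levels, with genes missing from a table set to 0 there. Where a group held 0 counts, the fold was computed against a floor of 3 counts over the group and is a lower bound. Folds of genes with 1 to 3 counts in a group are not given. Floors cover counting error only, since reads without molecular identifiers are not independent molecules.

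Before the data were examined, 33 gene lists were fixed (pathways, cell type markers, zonation, sex-biased genes, stress, clock, and markers of tissue handling, RNA quality and adjacent tissue). Lists with at least 5 tested members were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Named genes followed a rule fixed at the same time: Inhba and Gpnmb; the 6 highest and the 6 lowest log2 fold changes among called genes with a mean log2 CPM of at least 1, non-overlapping groups and a plain gene symbol; from each list with at least 3 called members the 3 with the smallest p; from other lists the called members, or the member with the smallest p where none was called; list members called against the direction of the others; and for each pair of comparisons 5 genes per direction with the smallest product of p-values. Genes outside the rule are marked as chosen after their values were seen. Some genes under the rule are not reported here.

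Agreement between comparisons was measured over genes tested in both as Pearson's correlation and the covariance of log2 fold changes, and as genes called in both by direction. The diet and Activin A comparisons share the NASH diet GFP libraries, so unchanged groups were simulated 50 times against these libraries for the correlation and covariance and 10 times with full fits for shared calls. One fit over all 5 groups gave the difference between the Activin A and the Gpnmb effect and the difference between the NASH diet controls.

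The procedure was tested on simulated data with 200 genes changed among the genes of each comparison. In the diet simulation (14388 genes), 5.97% of genes changed 1.5-fold, 41.8% of genes changed 2-fold and 83.3% of genes changed 4-fold were called in the right direction. The Activin A simulation (14598 genes) gave 19.4%, 46.3% and 90.9% at these folds, and the Gpnmb simulation (14845 genes) 58.2%, 77.6% and 87.9%. Unchanged genes made up 7.45%, 5.46% and 5.70% of the calls. Fewer genes were changed in the simulations than were called in the real comparisons. Adjusted p-values depend on the share of genes changed, so these rates need not hold for the real tests.

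Alternatives were relative log expression size factors, the Wald test of DESeq2 1.42.0, no filter, a minimum count of 50, all groups in one fit, the replicate number as a block, limma on log2 CPM (prior count 2), and each library left out in turn. Pseudocounts for normalized values did not apply, because the tables held counts. Library size without a composition factor, and the omission of NASH diet GFP libraries 2 and 3 together, were added after seeing the data. Figures were drawn with matplotlib 3.10.9.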

Results

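Liver transcripts were counted in 15 male C57BL/6J mouse samples, 3 in each of 5 groups. In the NASH diet arm, livers received GFP, Activin A, a scrambled hairpin or a hairpin against Gpnmb, and a further GFP group ate chow. Activin A is a secreted ligand of the transforming growth factor beta (TGF-beta) family and a dimer of the protein encoded by Inhba. Gpnmb encodes a transmembrane glycoprotein of macrophages and other cells. Total counts per sample ran from 15276879, in a chow library, to 23467867, in a scramble library. Albumin took 4.53% to 6.70% of the counts of a sample.

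Gpnmb (ENSMUSG00000029816, GRCm38 chromosome 6, 49036546 to 49070929) stood at 0.292 ± 0.171 CPM (SD, n = 3) in chow GFP livers and 30.6 ± 8.89 CPM in NASH diet GFP livers. It stood at 4.01 ± 1.47 CPM in Activin A livers, 31.4 ± 5.06 CPM in scramble livers and 2.02 ± 1.13 CPM in Gpnmb hairpin livers. The log2 fold change of Gpnmb was 6.70 ± 0.36 (SE) on the diet (edgeR adjusted p = 6.96e-06), -2.93 ± 0.27 under Activin A (edgeR adjusted p = 0.000731) and -3.95 ± 0.26 under its hairpin (edgeR adjusted p = 1.15e-05). Inhba (ENSMUSG00000041324, chromosome 13, 16011851 to 16031621) stood at 8.06 ± 0.114 CPM in NASH diet GFP livers and 25.0 ± 0.924 CPM in Activin A livers, a rise of 1.63 ± 0.11 on the log2 scale (edgeR adjusted p = 0.000192). Whether the Activin A transgene would be counted as Inhba is not given in the sources used here. Inhba stood between 9.45 and 12.7 CPM in the chow libraries, and its log2 fold change on the diet was -0.42 ± 0.19 (edgeR adjusted p = 0.176). Inhba rose by 0.92 ± 0.17 under the Gpnmb hairpin, from 5.49 ± 0.677 to 10.5 ± 1.69 CPM (edgeR adjusted p = 0.00325).

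**Figure D1:**
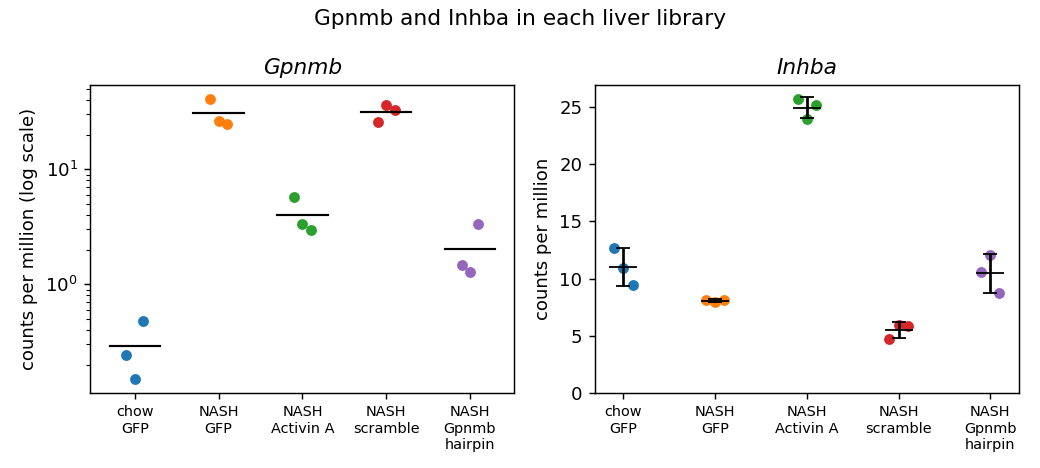
CPM of Gpnmb (log axis) and Inhba (linear axis) in each of the 15 libraries, by group, with horizontal lines at the group means and, for Inhba, error bars of 1 SD. Gpnmb lay at 24.9 CPM or above in every NASH diet GFP and scramble library and at 5.69 CPM or below in every Activin A, Gpnmb hairpin and chow library.

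The diet comparison asked which liver transcripts differed between the NASH diet and chow under the same GFP vector. On the NASH diet, transcripts of lipid-associated macrophages, inflammation and lipid storage rose, and transcripts of male-biased liver genes fell. Most matrix genes tested rose and most cholesterol synthesis genes fell. Camera's calls of these lists were lost with an estimated correlation, at an adjusted p = 0.108 and an adjusted p = 0.120. Fry called both lists (fry adjusted p = 0.00548 and 0.0126), among 16 higher and 4 lower on the diet. Mmp12, a macrophage elastase, rose by 7.20 ± 0.34 on the log2 scale (SE, n = 3 per group), the lipid droplet gene Cidec by 4.76 ± 0.24 and the collagen gene Col1a1 by 2.65 ± 0.27. Sqle, the squalene epoxidase of sterol synthesis, fell by 3.30 ± 0.32, and Selenbp2, a male-biased gene, fell by 4.67 ± 0.21. Of 14388 genes tested with edgeR, 1607 rose and 838 fell, 1235 and 390 of them by at least 2-fold. The 3 libraries of each group did not overlap for 35.0% of genes, against 10% by chance.

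Macrophage and immune transcripts rose together on the diet. Of 20 lipid-associated macrophage markers, 18 rose (18 higher and 1 lower adjusted over the list alone), among them the galectin gene Lgals3 (3.63 ± 0.25 on the log2 scale) besides Gpnmb and Mmp12. Camera called this list with an adjusted p of 5.77e-36. Of 12 monocyte and pan-macrophage markers 10 rose and 1 fell (11 and 1 adjusted over the list alone), including the lysozyme gene Lyz2 (2.01 ± 0.21) and the Fc receptor gene Fcgr3 (1.74 ± 0.20). F10, which encodes a coagulation factor, fell by 0.82 ± 0.16. Of 16 cytokine, chemokine and related inflammatory genes 11 rose (13 adjusted over the list alone), among them the adhesion molecule gene Vcam1 (2.41 ± 0.18) and Cxcl16 (1.66 ± 0.21). Of 23 interferon-stimulated genes 12 rose (14 adjusted over the list alone), among them Ifit2 (1.96 ± 0.28) and Gbp2 (1.60 ± 0.25). These macrophage, monocyte, inflammatory and interferon calls held with an estimated correlation, at adjusted p-values of 0.0202, 0.0202, 0.0202 and 0.0384.

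Of 30 extracellular matrix genes 28 rose (29 adjusted over the list alone), with Col1a2 at 2.12 ± 0.23 and Col3a1 at 2.11 ± 0.24 on the log2 scale. The camera call of the matrix list (adjusted p = 1.50e-21) was lost, at an adjusted p = 0.108 with an estimated correlation. Of 15 stellate cell and myofibroblast markers 8 rose (10 adjusted over the list alone), including the growth factor receptor genes Pdgfra (1.46 ± 0.20) and Pdgfrb (1.05 ± 0.17), with an adjusted p = 0.0552 with an estimated correlation. Proliferation genes rose in 11 of 22 cases (14 adjusted over the list alone), with the topoisomerase gene Top2a at 2.45 ± 0.40 (list adjusted p = 0.263 with an estimated correlation). Among p53 targets 9 of 15 rose (9 adjusted over the list alone), with Btg2 at 1.98 ± 0.24 (list adjusted p = 0.0623 with an estimated correlation). Ligands, inhibitors and targets of activin and TGF-beta signalling rose in 10 of 28 cases (11 higher and 1 lower adjusted over the list alone), with Tgfb1 at 1.48 ± 0.20 (list adjusted p = 0.0880 with an estimated correlation).

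Genes of lipid pathways moved in both directions on the diet, and of these lists only the lipid droplet call held with an estimated correlation. Lipid droplet genes rose in 13 of 18 cases (14 adjusted over the list alone), including the fatty acid transporter gene Cd36 (2.79 ± 0.30 on the log2 scale), and the call held at an adjusted p of 0.0202 with an estimated correlation. Of 24 genes of cholesterol synthesis 16 fell (20 adjusted over the list alone), among them Nsdhl (-2.34 ± 0.21) and Tm7sf2 (-2.05 ± 0.17), both of the later sterol steps. The camera call for cholesterol synthesis was lost, at an adjusted p = 0.120 with an estimated correlation. Of 24 oxidation genes and targets of the nuclear receptor PPARA 14 rose (15 adjusted over the list alone), with Pdk4 at 2.96 ± 0.23, the thioesterase gene Acot2 at 4.44 ± 0.41 and the hormone gene Fgf21 at 3.49 ± 0.45 (list adjusted p = 0.220 with an estimated correlation). Of 21 lipogenesis genes 5 rose and 2 fell (7 and 2 adjusted over the list alone), with the elongase gene Elovl5 at 1.98 ± 0.22, the desaturase genes Fads2 at 1.65 ± 0.23 and Scd1 at 2.52 ± 0.35, and Acss2 at -1.11 ± 0.21 (list adjusted p = 0.606 with an estimated correlation). Bile acid genes fell in 9 of 21 cases and rose in 3 (11 and 4 adjusted over the list alone), with the hydroxylase gene Cyp7b1 at -2.65 ± 0.30 and the sterol exporter gene Abcg5 at 1.23 ± 0.16 (list adjusted p = 0.220 with an estimated correlation).

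Sex-biased genes moved on the diet too. Some zonated hepatocyte genes also moved, but the calls of the zonated lists were lost with an estimated correlation. Of 16 male-biased genes 11 fell (13 adjusted over the list alone), with the antitrypsin family gene Serpina1e at -4.43 ± 0.24 on the log2 scale. Of 8 female-biased genes 7 rose and 1 fell (the same counts adjusted over the list alone), with the steroid hydroxylase gene Cyp17a1 at 2.86 ± 0.18. Both sex-biased calls held at an adjusted p of 0.0384 with an estimated correlation. Cyp2b9, which had 0 counts in the chow libraries, was at least 181-fold higher on the diet. Periportal genes fell in 9 of 15 cases and rose in 2 (9 and 2 adjusted over the list alone), with Gls2 at -1.12 ± 0.15 but the apolipoprotein gene Apoa4 at 5.01 ± 0.26 (list adjusted p = 0.441 with an estimated correlation). Of 15 pericentral genes 3 fell and 1 rose (4 and 1 adjusted over the list alone), with Cyp1a2 at -1.56 ± 0.16 (list adjusted p = 0.448 with an estimated correlation).

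Some markers of other cell types also differed, but no list call in this group of lists held with an estimated correlation. Kupffer cell markers rose in 4 of 11 cases and fell in 1 (the same adjusted over the list alone), with Cd5l at 2.04 ± 0.22 and C6, a complement gene, at -1.31 ± 0.18 on the log2 scale (list adjusted p = 0.444 with an estimated correlation). Sinusoidal endothelial markers rose in 3 of 14 cases (4 adjusted over the list alone), namely Pecam1 at 1.01 ± 0.16, Cdh5 at 1.01 ± 0.16 and Lyve1 at 1.93 ± 0.32 (list adjusted p = 0.448 with an estimated correlation). Biliary markers rose in 6 of 11 cases (7 adjusted over the list alone), with Ehf at 2.73 ± 0.40 (list adjusted p = 0.220 with an estimated correlation). T and natural killer (NK) cell markers rose in 2 of 8 cases (3 adjusted over the list alone), among them the chemokine gene Ccl5 at 2.53 ± 0.45 (list adjusted p = 0.213 with an estimated correlation). B and plasma cell markers rose in 2 of 11 cases (2 adjusted over the list alone; list adjusted p = 0.444 with an estimated correlation), and neutrophil markers in 3 of 4 (4 adjusted over the list alone), too few for camera. Lysosomal genes rose in 7 of 25 cases (10 adjusted over the list alone), with the cathepsin gene Ctss at 2.00 ± 0.23 (list adjusted p = 0.112 with an estimated correlation).

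Stress and handling lists were mixed on the diet. Immediate early genes, which respond to tissue handling among other stimuli, rose in 4 of 14 cases (4 adjusted over the list alone), with Klf6 at 2.09 ± 0.19 on the log2 scale (list adjusted p = 0.213 with an estimated correlation). Of 20 xenobiotic and NRF2 genes 6 rose and 2 fell (7 and 3 adjusted over the list alone), with Srxn1 at 1.71 ± 0.18 and Ces2a at -2.09 ± 0.21, and camera made no call (adjusted p = 0.475). Camera made no call for the unfolded protein and integrated stress response (2 of 17 higher, 4 lower, 2 and 6 adjusted over the list alone, adjusted p = 0.409), acute phase genes (3 of 21 higher, 1 lower, the same adjusted over the list alone and by limma, but 1 higher and 5 lower by DESeq2, adjusted p = 0.804), or pancreas, adipose and erythroid markers (3 of 7 higher, 3 lower, 4 and 3 adjusted over the list alone, adjusted p = 0.503). In these last 3 lists the median or mean log2 fold change was positive while camera's direction was down. Mitochondrially encoded transcripts had a median log2 fold change of -0.44, with 0 of 13 called by edgeR (5 at an unadjusted p under 0.05, 2 lower by DESeq2, 0 by limma). That list's camera call had an adjusted p = 0.220 with an estimated correlation, and the call of the respiratory chain list (1 of 31 lower, 0 adjusted over the list alone) an adjusted p = 0.576 with an estimated correlation. Of 17 clock genes edgeR called 0 (2 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma), and camera made no call (adjusted p = 0.804). The clock list had a median of -0.02, a mean of 0.10 and a camera direction of down.

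Without NASH diet GFP library 1 the diet counts were 971 higher and 384 lower, without chow library 1 they were 1030 and 487, and without NASH diet GFP library 2 the count of lower genes was 432. With library size alone as the scaling, 86.8% of calls were higher against 65.7% with TMM, and the median log2 fold change of all genes was 0.24 against -0.01.

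**Figure D2:**
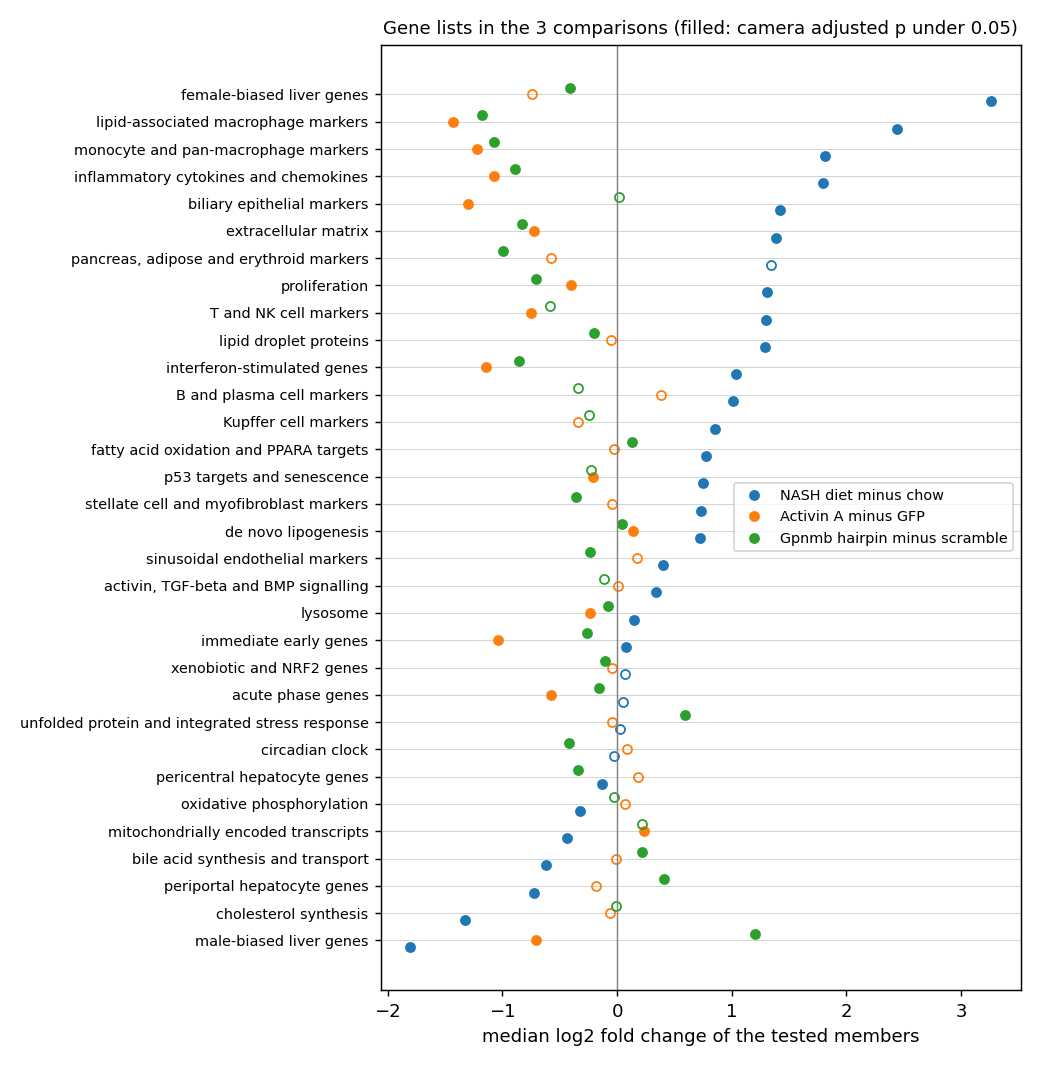
Median log2 fold change of the tested members of each fixed gene list (horizontal axis) in the diet, Activin A and Gpnmb hairpin comparisons, filled where camera's adjusted p was under 0.05 at the preset correlation. The lipid-associated macrophage list had a median of 2.44 on the diet, -1.43 under Activin A and -1.18 under the Gpnmb hairpin.

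The Activin A comparison asked how liver expression of Activin A changed the transcriptome on the NASH diet, against GFP. Activin A livers had lower transcripts of macrophages, interferon response and inflammation than GFP livers. Mmp12 fell by 2.68 ± 0.19 on the log2 scale (SE, n = 3 per group) and the macrophage gene Mpeg1 by 1.71 ± 0.10. The interferon regulatory factor gene Irf7 fell by 1.43 ± 0.14 and Vcam1 by 1.01 ± 0.12. Among the genes with the highest log2 fold changes were the transporter gene Slc13a4 (3.87 ± 0.22), Fsd2 (3.43 ± 0.28), Enho, which encodes the secreted peptide adropin (3.41 ± 0.17), and Prok1 (2.83 ± 0.30). Of 14598 genes tested with edgeR, 242 rose and 564 fell, 87 and 354 of them by at least 2-fold. Libraries of the groups did not overlap for 25.9% of genes, against 10% by chance.

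Lipid-associated macrophage markers fell in 17 of 20 cases under Activin A (19 adjusted over the list alone), among them Lgals3 (-2.14 ± 0.20 on the log2 scale), Mmp12 and Gpnmb. Monocyte and pan-macrophage markers fell in 9 of 13 cases (10 adjusted over the list alone), with Cd14 at -2.09 ± 0.22 and Lyz2 at -1.34 ± 0.14. Interferon-stimulated genes fell in 18 of 23 cases (21 adjusted over the list alone), with Oasl1 at -1.50 ± 0.17 and the chemokine gene Cxcl9 at -1.15 ± 0.14. Inflammatory cytokine and chemokine genes fell in 6 of 17 cases (16 adjusted over the list alone). Lysosomal genes fell in 4 of 25 cases (11 adjusted over the list alone), with Ctss at -1.32 ± 0.11. These macrophage, monocyte, interferon, inflammatory and lysosomal calls held with an estimated correlation, at adjusted p-values of 0.0110, 0.0101, 0.00790, 0.0138 and 0.0498.

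Of the extracellular matrix genes 12 of 30 fell under Activin A (22 adjusted over the list alone), with Col1a1 at -1.56 ± 0.24, Col1a2 at -1.14 ± 0.17 and the thrombospondin gene Thbs1 at -1.90 ± 0.30 on the log2 scale (list adjusted p = 0.256 with an estimated correlation). Acute phase genes fell in 8 of 21 cases (1 higher and 11 lower adjusted over the list alone), with the interleukin receptor antagonist gene Il1rn at -2.33 ± 0.23 and the pentraxin gene Apcs at -1.21 ± 0.12 (list adjusted p = 0.415 with an estimated correlation). The serum amyloid gene Saa2 stood at 330 ± 488 CPM (SD) in GFP livers, with 894 CPM in library 2, and at 11.4 ± 2.31 CPM in Activin A livers. The Saa2 call (-4.86 ± 1.09) was lost without any of the Activin A libraries, and the log2 fold change was -2.09 without GFP library 2. Biliary markers fell in 3 of 11 cases (9 adjusted over the list alone), with Ehf at -2.29 ± 0.36 (list adjusted p = 0.245 with an estimated correlation). Immediate early genes fell in 3 of 14 cases (5 adjusted over the list alone), with Klf6 at -1.30 ± 0.16 (list adjusted p = 0.200 with an estimated correlation).

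Male-biased genes fell in 7 of 16 cases and rose in 2 under Activin A (the same adjusted over the list alone), with Cyp4a12a at -1.45 ± 0.18 and Mup20 at -0.79 ± 0.10 but Serpina1e at 1.23 ± 0.16 on the log2 scale (list adjusted p = 0.461 with an estimated correlation). Female-biased genes fell in 2 of 8 cases and rose in 1 (3 and 1 adjusted over the list alone), with Cyp17a1 at -1.46 ± 0.15, and camera made no call (adjusted p = 0.0558). Of 28 genes of activin and TGF-beta signalling 4 rose and 2 fell (7 and 4 adjusted over the list alone). The risers included Inhba, whose rise may be the transgene itself, if it was counted as Inhba. The related subunit gene Inhbc (0.90 ± 0.11) and the activin inhibitor gene Fst (1.14 ± 0.17) rose too, and camera made no call for the list (adjusted p = 0.0879). That list's median was 0.01 and its mean -0.01. Clock genes rose in 2 of 16 cases and fell in 1 (3 and 1 adjusted over the list alone), with Cry1 at 1.56 ± 0.20 (camera adjusted p = 0.115).

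Other Activin A list calls were lost with an estimated correlation. These were proliferation (3 of 24 lower, 7 adjusted over the list alone, Cdc20 at -2.37 ± 0.37 on the log2 scale, adjusted p = 0.708 with an estimated correlation), p53 targets (2 of 15 lower and 1 higher, 5 and 1 adjusted over the list alone, Btg2 at -0.89 ± 0.14, adjusted p = 0.288 with an estimated correlation) and T and NK cell markers (1 of 9 lower, 1 adjusted over the list alone, adjusted p = 0.353 with an estimated correlation). Higher by camera were lipogenesis (2 of 22 higher, 2 adjusted over the list alone, adjusted p = 0.708 with an estimated correlation) and mitochondrially encoded transcripts, of which edgeR called 0 of 13 (2 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma, adjusted p = 0.708 with an estimated correlation). Of 24 cholesterol synthesis genes edgeR called 0 under Activin A (3 at an unadjusted p under 0.05, 1 higher and 1 lower by DESeq2, 0 by limma). Camera made no call for cholesterol synthesis (adjusted p = 0.891).

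Camera also made no call under Activin A for the lists that follow. Periportal genes fell in 3 of 15 cases (1 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0638), with Cyp2f2 at -1.21 ± 0.15 on the log2 scale. Of 15 pericentral genes 1 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.159), the latter Rhbg at -2.27 ± 0.36. Sinusoidal endothelial markers (1 of 14 higher, 1 lower, the same adjusted over the list alone, camera adjusted p = 0.261) included Lyve1 at -1.47 ± 0.23. Lipid droplet genes fell in 3 of 18 cases (1 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.274), with Plin3 at -0.60 ± 0.09. Bile acid genes rose in 2 of 21 cases and fell in 2 (2 and 4 adjusted over the list alone, camera adjusted p = 0.830), with Abcg8 at 0.89 ± 0.14 and Akr1d1 at -0.81 ± 0.12. The bile acid median was -0.01 and the mean -0.07, with a camera direction of up. Of 17 stress response genes 1 rose and 1 fell (the same adjusted over the list alone, camera adjusted p = 0.284), the latter Atf3 at -1.61 ± 0.20. Pancreas, adipose and erythroid markers fell in 1 of 8 cases (1 adjusted over the list alone, camera adjusted p = 0.115), namely Car3 at -1.21 ± 0.16.

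Nor did camera call 7 further lists under Activin A, of which neutrophil markers were too few to test. Xenobiotic genes fell in 5 of 20 cases and rose in 1 (6 and 2 adjusted over the list alone, camera adjusted p = 0.493). Kupffer cell markers fell in 2 of 11 cases and rose in 1 (3 and 2 adjusted over the list alone, camera adjusted p = 0.115). Stellate cell markers fell in 1 of 15 cases (2 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.830). Of 24 oxidation genes 1 rose and 1 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.891). EdgeR called 0 of 4 neutrophil markers (3 at an unadjusted p under 0.05, 3 lower adjusted over the list alone, 0 by DESeq2 and 0 by limma). Of 11 B and plasma cell markers edgeR called 0 (2 at an unadjusted p under 0.05, 2 higher adjusted over the list alone, 1 higher by DESeq2 and 1 by limma, camera adjusted p = 0.117). Of 31 respiratory chain genes edgeR called 0 (0 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma, camera adjusted p = 0.0558).

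Leaving out Activin A library 1, 2 or 3 gave 87, 106 and 68 higher and 206, 266 and 180 lower genes, and leaving out GFP library 3 gave 535 and 900. DESeq2 called 364 genes higher, and without a filter 372 were higher and 881 lower.

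The Gpnmb comparison asked how a hairpin against Gpnmb changed the liver transcriptome on the NASH diet, against a scrambled hairpin. Many macrophage, matrix, interferon and proliferation genes fell in Gpnmb hairpin livers, many male-biased genes rose, and clock genes moved in both directions. The camera calls of these lists were lost, with adjusted p-values from 0.146 (male-biased) to 0.271 with an estimated correlation. The integrin gene Itgax fell by 2.47 ± 0.23 on the log2 scale (SE, n = 3 per group), Trem2, a lipid receptor gene of macrophages, by 2.33 ± 0.25 and Col1a1 by 1.74 ± 0.23. Among the highest rises were Serpina1e (3.41 ± 0.10), the leptin receptor gene Lepr (3.19 ± 0.17), and Asns, the asparagine synthetase gene (3.06 ± 0.27). Serpina1e also lay lower in scramble than in GFP control livers (-2.31 ± 0.15). Of 14845 genes tested with edgeR, 1813 rose and 1788 fell, 199 and 615 of them by at least 2-fold. Libraries of the groups did not overlap for 40.9% of genes, against 10% by chance.

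None of the list calls under the Gpnmb hairpin held with an estimated correlation, where 2 lists were higher and 3 lower at an unadjusted p under 0.05, while fry called 4 higher and 17 lower. Lipid-associated macrophage markers fell in 15 of 20 cases and rose in 1 (16 and 1 adjusted over the list alone, adjusted p = 0.271 with an estimated correlation). Gpnmb, the target of the hairpin, is counted among the 15. Monocyte and pan-macrophage markers fell in 10 of 13 cases (11 adjusted over the list alone, adjusted p = 0.245 with an estimated correlation), with Lyz2 at -1.35 ± 0.11 and the chemokine receptor gene Ccr2 at -2.12 ± 0.25 on the log2 scale. Of 30 extracellular matrix genes 24 fell and 2 rose (27 and 2 adjusted over the list alone, adjusted p = 0.271 with an estimated correlation), with Sparc at -1.07 ± 0.12 and Col5a2 at -1.53 ± 0.21, while the fibronectin gene Fn1 stood at 0.50 ± 0.08. Interferon-stimulated genes fell in 18 of 23 cases (19 adjusted over the list alone, adjusted p = 0.271 with an estimated correlation), with Ifit3 at -1.23 ± 0.17 and Ifit2 at -1.12 ± 0.15. Inflammatory genes fell in 10 of 17 cases (12 adjusted over the list alone, adjusted p = 0.271 with an estimated correlation), with Vcam1 at -0.71 ± 0.10. Proliferation genes fell in 11 of 24 cases (14 adjusted over the list alone, adjusted p = 0.245 with an estimated correlation), with Mki67, the Ki-67 antigen gene, at -1.77 ± 0.20. Stellate cell markers fell in 7 of 15 cases (8 adjusted over the list alone, adjusted p = 0.271 with an estimated correlation), with the smooth muscle actin gene Acta2 at -1.41 ± 0.22 and Lrat, of retinoid storage, at -0.91 ± 0.13. Lysosomal genes fell in 9 of 25 cases and rose in 3 (9 and 4 adjusted over the list alone, adjusted p = 0.290 with an estimated correlation), with Ctss at -1.06 ± 0.09.

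Male-biased genes rose in 12 of 16 cases and fell in 1 under the Gpnmb hairpin (14 and 1 adjusted over the list alone, adjusted p = 0.146 with an estimated correlation), among them Elovl3 at 2.18 ± 0.18 and Cyp7b1 at 1.93 ± 0.14 on the log2 scale. Female-biased genes fell in 4 of 10 cases and rose in 3 (6 and 3 adjusted over the list alone, adjusted p = 0.271 with an estimated correlation), with Cyp17a1 at -1.13 ± 0.17 and Cyp4a14 at 0.97 ± 0.14. Genes of the unfolded protein and integrated stress response rose in 10 of 17 cases and fell in 1 (11 and 1 adjusted over the list alone, adjusted p = 0.245 with an estimated correlation), with the chaperone gene Dnajb9 at 1.15 ± 0.10 and the transcription factor gene Atf3 at -2.60 ± 0.34. In one fit of all groups this stress list lay lower in scramble than in GFP control livers (median -0.72, 2 of 17 genes lower, camera adjusted p = 8.59e-12, but adjusted p = 0.144 with an estimated correlation), against a median of 0.60 for the hairpin minus scramble livers. Periportal genes rose in 8 of 15 cases and fell in 2 (9 and 2 adjusted over the list alone, adjusted p = 0.271 with an estimated correlation), with the gluconeogenic genes Pck1 at 1.26 ± 0.12 and G6pc at 1.25 ± 0.13. Pericentral genes fell in 8 of 15 cases (8 adjusted over the list alone, adjusted p = 0.271 with an estimated correlation), with the glutamine synthetase gene Glul at -0.62 ± 0.09. Bile acid genes rose in 9 of 20 cases and fell in 2 (9 and 2 adjusted over the list alone, adjusted p = 0.370 with an estimated correlation), and oxidation genes rose in 8 of 24 cases and fell in 2 (9 and 2 adjusted over the list alone, adjusted p = 0.392 with an estimated correlation).

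Of 17 clock genes 4 rose and 10 fell under the Gpnmb hairpin (4 and 11 adjusted over the list alone, adjusted p = 0.271 with an estimated correlation). The activator genes Arntl (1.79 ± 0.20 on the log2 scale), Npas2 (1.91 ± 0.27) and Clock (0.93 ± 0.09) and the repressor gene Nfil3 (1.61 ± 0.09) rose, while the period genes Per3 (-2.60 ± 0.14) and Per2 (-1.32 ± 0.09) fell. Lipogenesis genes fell in 7 of 22 cases and rose in 3 (7 and 4 adjusted over the list alone, adjusted p = 0.271 with an estimated correlation), with the lipogenic regulator gene Thrsp at -3.18 ± 0.15. The lipogenesis list had a median of 0.04 but a mean of -0.30 and a camera direction of down. On a clock index described in the closing section, the scramble control libraries lay at -3.55 to -3.26, below the range of -2.91 to -0.73 of the 9 chow, GFP and Activin A libraries. Gpnmb hairpin libraries 1 and 2, at -0.58 and -0.52, lay above that range, and hairpin library 3, at -1.27, lay inside it. The collection time and feeding state of the livers are not in the labels.

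**Figure D3:**
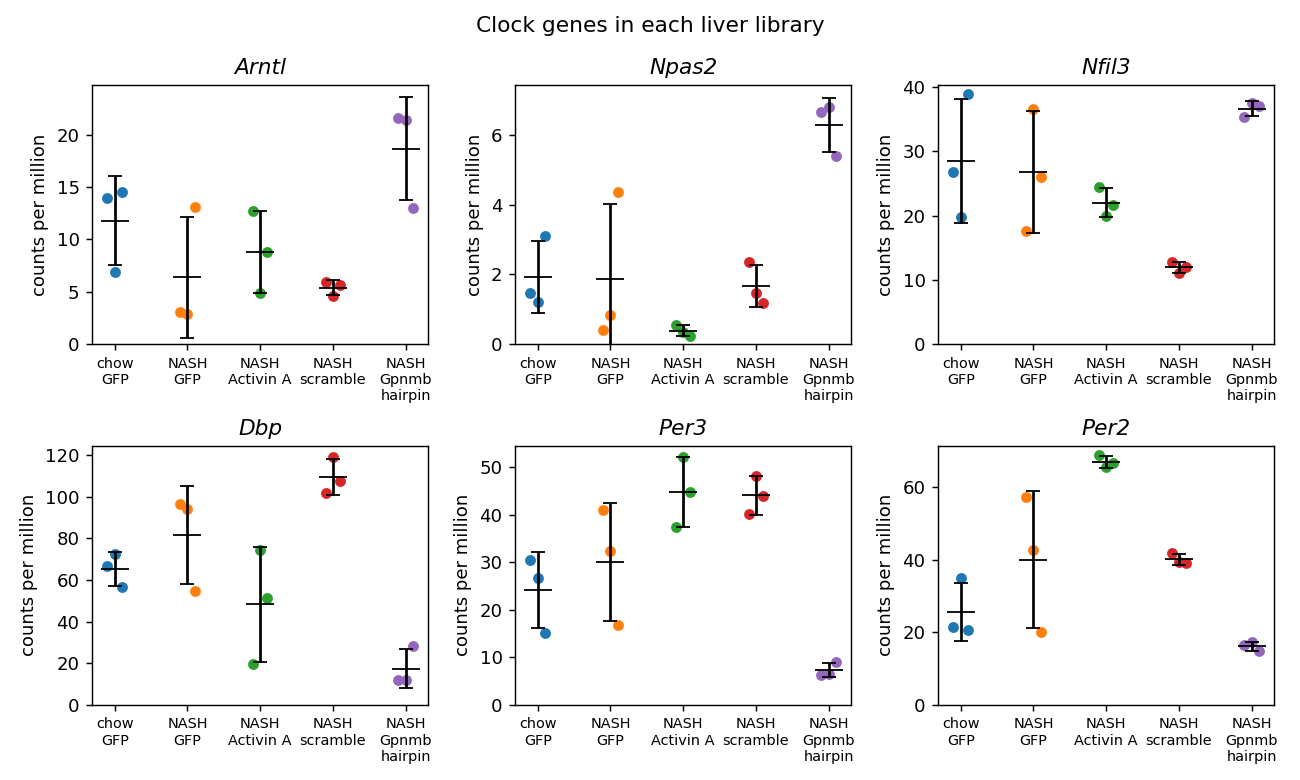
CPM of clock genes in each library, by group, with group means and error bars of 1 SD on linear axes. Arntl, Npas2 and Nfil3 rose and Per3 and Per2 fell in hairpin against scramble livers. On an index of clock genes the scramble livers lay below all chow, GFP and Activin A livers, and Gpnmb hairpin libraries 1 and 2 lay above them.

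Acute phase genes moved both ways under the Gpnmb hairpin, with 10 of 21 lower and 5 higher (the same adjusted over the list alone, adjusted p = 0.357 with an estimated correlation). Lcn2, an iron carrier gene, stood at -2.41 ± 0.20 and Orm2 at -2.58 ± 0.25 on the log2 scale, and the fibrinogen genes Fga, Fgg and Fgb at 0.86 ± 0.09, 0.72 ± 0.09 and 0.65 ± 0.09. Lipid droplet genes fell in 8 of 18 cases and rose in 1 (10 and 2 adjusted over the list alone, adjusted p = 0.357 with an estimated correlation), with Mogat1 at -2.26 ± 0.26 and Cd36 at -0.62 ± 0.07. Xenobiotic genes fell in 6 of 20 cases and rose in 2 (7 and 3 adjusted over the list alone, adjusted p = 0.271 with an estimated correlation), with Cyp2b10 at -4.35 ± 0.46 and Nqo1 at -1.10 ± 0.13. Sinusoidal endothelial markers fell in 5 of 14 cases (5 adjusted over the list alone, adjusted p = 0.469 with an estimated correlation), with Stab1 at -0.36 ± 0.08. In one fit of all groups 4 further lists differed between scramble and GFP controls opposite to their change under the hairpin. These were sinusoidal (median 0.24, camera adjusted p = 0.00131, adjusted p = 0.455 with an estimated correlation), pericentral (0.18, camera adjusted p = 0.00579), periportal (-0.29, camera adjusted p = 0.00131) and female-biased genes (0.37, camera adjusted p = 0.0461), the last 3 with an adjusted p = 0.410 with an estimated correlation. Other lists differed between these controls in camera's direction under the hairpin. Lower were acute phase (camera adjusted p = 4.37e-07), lipogenesis (0.00264), immediate early (0.00813), xenobiotic (0.0164) and proliferation genes (0.0181). Higher were oxidation genes (camera adjusted p = 0.0377). With an estimated correlation the adjusted p-values of these lists ran from 0.410 to 0.665. Immediate early genes fell in 5 of 14 cases and rose in 2 (6 and 2 adjusted over the list alone, adjusted p = 0.271 with an estimated correlation), with Klf6 at -1.15 ± 0.15 but the heat shock gene Hspa1b at 2.28 ± 0.32. Pancreas, adipose and erythroid markers fell in 4 of 8 cases and rose in 1 (6 and 1 adjusted over the list alone, adjusted p = 0.276 with an estimated correlation), with the globin gene Hbb-bs at -1.96 ± 0.27.

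Camera made no call under the Gpnmb hairpin for the lists that follow. Mitochondrially encoded transcripts rose in 2 of 12 cases (2 adjusted over the list alone, camera adjusted p = 0.0592), with mt-Nd2 at 0.57 ± 0.11 on the log2 scale. Genes of activin and TGF-beta signalling rose in 5 of 28 cases and fell in 7 (7 and 7 adjusted over the list alone, camera adjusted p = 0.422), with the subunit gene Inhbe at -0.99 ± 0.14. Cholesterol synthesis genes rose in 3 of 23 cases and fell in 4 (5 and 8 adjusted over the list alone, camera adjusted p = 0.713), with Cyp51 at 0.84 ± 0.10. Kupffer cell markers rose in 2 of 11 cases and fell in 3 (2 and 5 adjusted over the list alone, camera adjusted p = 0.338), with C6 at 1.03 ± 0.08 and Cd5l at -0.98 ± 0.11. Respiratory chain genes fell in 3 of 31 cases (3 adjusted over the list alone, camera adjusted p = 0.303), with Ndufa2 at -0.43 ± 0.07. The biliary marker Tm4sf4 fell by 0.51 ± 0.08, 1 of 11 (1 adjusted over the list alone, camera adjusted p = 0.432). The biliary median was 0.01 and the mean -0.26, with a camera direction of down. Of 15 p53 targets 2 rose and 3 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.338).

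Lymphocyte and neutrophil markers were sparse in the hairpin comparison. Of 7 T and NK cell markers 1 rose (0 adjusted over the list alone, camera adjusted p = 0.602), and of 3 neutrophil markers 1 fell (1 adjusted over the list alone). Of 8 B and plasma cell markers edgeR called 0 (1 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma, camera adjusted p = 0.391).

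Leaving out scramble library 2 gave 1092 higher and 1122 lower genes, and leaving out scramble library 3 gave 929 and 994, while all groups in one fit gave 835 and 1045. With library size alone as the scaling, 29.0% of calls were higher against 50.3% with TMM, and the median log2 fold change of all genes was -0.11 against 9e-04.

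The last comparison asked whether genes moved by the diet moved back under Activin A or the Gpnmb hairpin. Among 1607 genes higher on the diet, 371 fell and 41 rose under Activin A. Under the Gpnmb hairpin 744 of 1584 such genes fell and 70 rose, with a median log2 fold change of -0.57 and 85.0% below 0 (camera p = 0.0651 with an estimated correlation, fry p = 0.00627). Of 803 genes lower on the diet 246 rose and 53 fell under the Gpnmb hairpin (camera p = 0.250 with an estimated correlation), and of 784 such genes 41 rose and 28 fell under Activin A. No set test is given for Activin A, because its GFP controls also chose the sets. Mmp12 and Clec7a, a receptor gene for fungal glucans, rose on the diet and fell under both treatments, as did Gpnmb, the target of the hairpin. Serpina1e fell on the diet and rose under both, and Lepr rose in all 3 comparisons (3.40 ± 0.34, 1.62 ± 0.26 and 3.19 ± 0.17 on the log2 scale). Car3, a carbonic anhydrase gene, fell on the diet (-1.45 ± 0.19) and under Activin A (-1.21 ± 0.16).

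**Figure D4:**
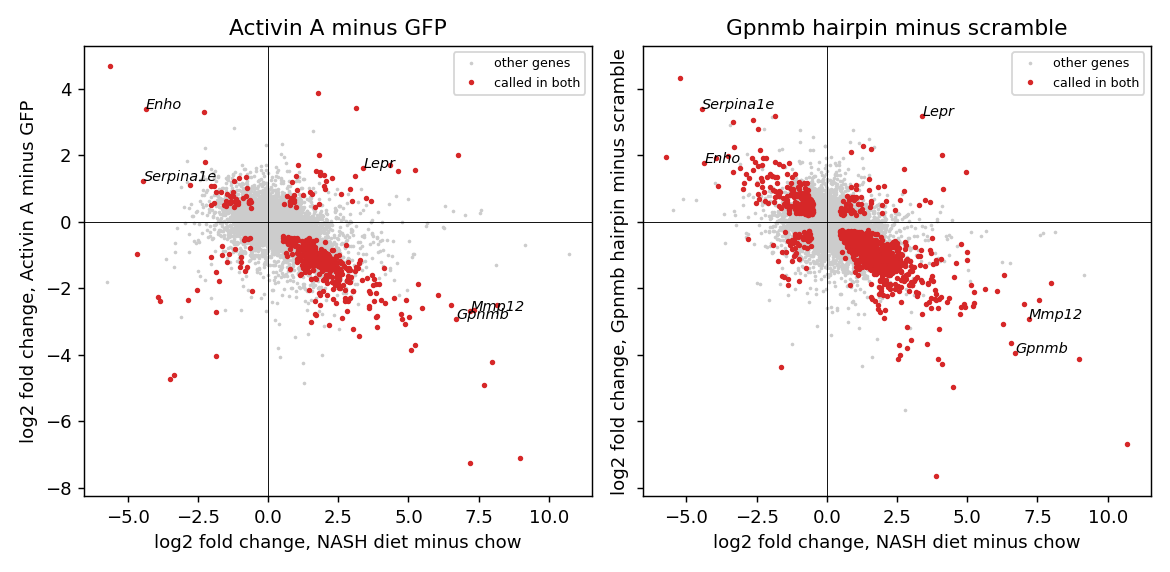
Log2 fold change of each gene on the diet (horizontal axis) against its log2 fold change under Activin A (left) or the Gpnmb hairpin (right), with genes called in both comparisons in red. In the lower right quadrant 371 genes were called under Activin A and 744 under the Gpnmb hairpin.

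Genes called in opposite directions on the diet and under Activin A numbered 412 (371 higher on the diet and 41 lower), against 63.9 and 12.7 for independent lists. Pearson's correlation of the fold changes across 14166 genes, which are not independent replicates, was -0.48 (Spearman's rho -0.39). The NASH diet GFP libraries enter both comparisons with opposite sign, and simulated unchanged groups against them gave a mean correlation of -0.49 and a mean covariance of -0.04, against an observed covariance of -0.22, a difference of -0.17. The simulated fold changes were ratios of group means with a small constant added, not edgeR estimates. Genes were drawn independently of each other, with their spread averaged over both comparisons. The simulated covariances thus set no firm bound on what the shared libraries could give. Simulated fits gave 0 genes called in opposite directions in edgeR. They held no diet effect, so few calls were possible in either comparison, and they set no chance level for the 412 calls. The 3 shared libraries are too few to split, so part of the excess of shared calls may come from them. Without Activin A libraries 1, 2 or 3 the opposite calls numbered 162, 206 and 139, and without GFP libraries 1 or 3 they numbered 237 and 665. The diet and Gpnmb hairpin comparisons share no library, and their opposite calls numbered 990 (744 and 246, against 195 and 102 for independent lists), with a correlation of -0.50, a rho of -0.37 and a covariance of -0.24. Without scramble library 2 or 3 these numbered 641 and 634.

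Activin A and the Gpnmb hairpin, which share no library, lowered 322 genes in common against 68.4 for independent lists and raised 46 against 28.6, with 84 called in opposite directions (correlation 0.31 and rho 0.23 across 14239 genes). Ctss, Clec7a and Aldh1b1, a mitochondrial aldehyde dehydrogenase gene, were among the genes that fell under both, and Enho, Peg3 and Inhba among those that rose. The rise of Inhba under Activin A may be the transgene itself, if it was counted as Inhba. The shared calls in the same direction numbered 150, 194 and 134 without Activin A libraries 1, 2 or 3, and 232 and 606 without GFP libraries 1 or 3. A test of the difference between the effects, with all groups in one fit, called 297 genes with a higher and 336 with a lower effect of Activin A. Male-biased genes had a lower effect of Activin A in 10 of 16 cases and a higher one in 1, with a median difference of -2.17 on the log2 scale (adjusted p = 0.0280 with an estimated correlation). Cyp4a12a and Mup20 fell under Activin A and rose under the Gpnmb hairpin (0.69 ± 0.10 and 1.46 ± 0.19).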

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

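Library size alone as the scaling and the joint omission of NASH diet GFP libraries 2 and 3 were chosen only after the data were seen. With one library left out, diet counts ran from 971 to 1472 higher and 384 to 797 lower, Activin A counts from 68 to 535 and 180 to 900, and Gpnmb hairpin counts from 929 to 1685 and 994 to 1811. Opposite calls ran from 139 to 665 (Activin A and diet) and 634 to 1003 (hairpin and diet), and calls in the same direction (Activin A and hairpin) from 134 to 606. All groups in one fit gave 2475 and 2025 on the diet and 835 and 1045 under the hairpin. Library size alone gave 2671 and 405 on the diet and 1006 higher under the hairpin. Without NASH diet GFP libraries 2 and 3, counts were 665 and 305 on the diet and 424 higher under Activin A, with the lone GFP library assumed to vary like the others. For Activin A, DESeq2 gave 364 higher, and no filter 372 higher and 881 lower. With an estimated correlation, lists called by camera fell from 20 higher and 7 lower to 6 and 1 on the diet. They fell from 2 and 13 to 0 and 5 under Activin A, and from 5 and 18 to 0 and 0 under the hairpin. Fry gave 16 higher and 4 lower on the diet, 0 and 7 under Activin A, and 4 and 17 under the hairpin. Fewer samples enter the fits without libraries, but this would not raise counts as the omission of GFP library 3 did for Activin A. The cause of the shifts was not tested. The replicate block gave 467 lower genes on the diet and moved no other count over 1.5 times; samples of the same number correlated at -0.15 to 0.04 in their deviations, so the numbers do not pair them. With 1 library left out, 15 of 110 genes named for the diet, 40 of 94 for Activin A and 28 of 132 for the hairpin no longer passed. All groups in one fit ended 41 of 132 hairpin genes, library size alone 15 of 132, and the omission of NASH diet GFP libraries 2 and 3 ended 30 of 110 diet genes, and 0 reversed under any alternative run. Pseudocounts for normalized values did not apply.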

Other observations

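The tests of the shared NASH diet GFP libraries and of the level of Gpnmb left in the treated livers, and the genes named in the next paragraph, were chosen only after the results were seen.

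Some immunoglobulin transcripts differed between groups, although no list of immunoglobulin genes was fixed or tested. Ighm stood at 84.1 ± 8.75 CPM (SD, n = 3) in Activin A livers, 34.4 ± 18.3 CPM in NASH diet GFP livers and 14.7 ± 1.59 CPM in chow livers, against 9.17 ± 0.836 CPM in scramble and 7.59 ± 0.757 CPM in Gpnmb hairpin livers. Igkc rose under Activin A by 1.27 ± 0.29 on the log2 scale (edgeR adjusted p = 0.0342), while the adjusted p of Ighm was 0.0544. Ighg1, a gene under the naming rule, rose by 4.52 (edgeR adjusted p = 0.00482), with estimates of 3.89 to 4.92 over the alternatives. In one fit of all groups the scramble control lay below the GFP control for Igkc (-2.18 ± 0.28), Jchain (-2.66 ± 0.35) and Ighm (-1.91 ± 0.28), among 89 lower and 27 higher genes. The B and plasma cell list, which holds Jchain and Ighm, had 2 of 11 genes lower in this contrast (camera adjusted p = 4.99e-07). That call was lost, at an adjusted p = 0.3035 with an estimated correlation. The liver gene Igfbp1 differed by -2.25 ± 0.20 and Serpina1e by -2.31 ± 0.15 in the same contrast. Thrsp stood at 44.0 CPM in NASH diet GFP library 3, against 802 and 447 CPM in libraries 1 and 2.

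Clock genes shifted between the hairpin groups. An index, the median level of Arntl, Npas2, Clock, Nfil3 and Cry1 minus that of 9 Per, Nr1d and output genes, averaged -3.38 in scramble livers, with every library below the range of -2.91 to -0.73 in the 9 chow, GFP and Activin A libraries, and -0.79 in Gpnmb hairpin livers, of which 2 of 3 lay above that range. Every Gpnmb hairpin library, at -1.27 to -0.52, lay above every chow and GFP library (-2.91 to -1.81). Both hairpin groups thus lay outside the range of the chow and GFP libraries. That narrower range was not in the prediction written beforehand, which used all 9 libraries. With all 9 the prediction was not decided, since hairpin library 3 lay inside their range and the other hairpin libraries above it. Whether the scramble livers alone stand apart stays open, since the upper end of the full range is a single Activin A library. Collection at another time of day or feeding state may account for the shift, and rhythmic genes outside the fixed lists had a median log2 fold change of -2.17 (Usp2 -2.37 ± 0.13, Wee1 -2.17 ± 0.15, but Lonrf3 0.68 ± 0.33, adjusted p = 0.161 by edgeR). Such a difference cannot be told apart from an effect of the hairpin on the clock. Collection times are not in the labels, and a whole group would share them. The same limit holds for the other genes called between the hairpin groups, and so for their agreement with the other comparisons.

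Gpnmb fell with other lipid-associated macrophage markers under both treatments, and fewer such macrophages may account for this. Of the control level above the chow GFP mean, 12.2% of Gpnmb was left in Activin A livers and 5.55% in Gpnmb hairpin livers. The medians of the other list members called higher on the diet were 24.9% and 25.9%. The control was NASH diet GFP for Activin A and scramble for the hairpin. Scramble and chow GFP livers carried different vectors, so the hairpin share is not a diet contrast under the same vector. Lower shares than Gpnmb were left of Spp1 (-8.84%), Ms4a7 (-0.594%) and Mmp13 (11.1%) under Activin A, and of Ms4a7 (0.973 ± 7.51%, SD) under the hairpin, so the level of Gpnmb did not lie below all other markers. In hairpin livers 98.3% of Cd9 and 108% of Lpl were left, and 89.8% of Lpl in Activin A livers, which goes against an even loss of all markers, although other cells express both genes. A direct action of the hairpin on Gpnmb stays open, since these shares do not separate it from a loss of cells.

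Of the genes raised by the diet, 371 of 1607 fell under Activin A and 744 of 1584 under the Gpnmb hairpin. Under Activin A the covariance of -0.22 with the diet lay below -0.04, the lowest value simulated for the shared GFP libraries alone. That simulation drew genes independently of each other, so it does not exclude a larger part from libraries whose genes vary together. A loss of the diet response may be what both treatments share, which predicted a correlation of their fold changes within 0.1 of 0 among genes not called on the diet. The correlation was 0.16 over 11631 such genes, past the bound set before it was computed. Genes not called can still hold diet responses, since the diet simulation called 41.8% of genes changed 2-fold. Over 3944 genes with an unadjusted diet p of at least 0.5, a set chosen after the first value was seen, the correlation was 0.02. With the correlation of 0.16 the prediction as written was not met. Among the 11631 genes, 21 rose and 58 fell under both treatments, and 50 were called in opposite directions. The smaller set, chosen late, cannot overturn the missed prediction. Both sets were chosen by diet p-values, which rest on the same GFP libraries as the Activin A fold changes. Neither correlation is therefore free of these libraries. Whether uncalled diet responses explain the miss was not tested, and whether the treatments share more than a loss of the diet response stays open.

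For each comparison the 6 samples make 10 splits into 3 and 3, too few for a share under 0.05. The real split, 1 of 10, called 2445 genes for the diet, 806 for Activin A and 3601 for the Gpnmb hairpin with edgeR, and the highest of the other splits called 0 in each (at most 1058, 801 and 696 at an unadjusted p under 0.05). The other splits mix both groups on each side, so a group difference widens the spread within sides and lowers their calls. The 0 is thus no measure of how many calls chance would give.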
